A study of Mus musculus with 6 samples.

How the data were processed

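MiRNA abundance was measured in retinal cells of B10.RIII mice, in 3 naive samples and 3 samples of mice developing EAU on day 14, per the labels. Total RNA (800 ng) of each sample was labelled with Hy3 and a shared pool of equal amounts of the samples with Hy5, and both were hybridised to a miRCURY LNA array, per the labels. All 6 arrays have the same dye orientation, and no dyes were swapped. The labels state that the samples were harvested independently but not how many mice each holds, so the p-values measure the spread between harvests.

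The authors deposited one scanner output file per array. Each holds the intensity of 8720 spots in 2 channels with the local background, made with Agilent Feature Extraction 9.1.3.1, per the file headers. The submitters' processing notes name Agilent Feature Extraction without a version. The processed intensity columns were background-adjusted and dye-normalized by that program, per the file headers. The authors also deposited a table of a linear ratio per probe, with 1972 rows. Set against the scanner values, its values follow Hy3 over Hy5 on a linear scale: over 596 probes bright on all arrays, the median correlation across the 6 arrays with the ratio of the processed signals was 0.951. The medians of its columns were 0.879, 0.851 and 0.769 for naive replicates 1 to 3 and 0.809, 0.886 and 0.807 for EAU replicates 1 to 3. Its exact normalization and centring are not given in the sources used here. In 36 rows the ratio lay above 32 on every array, against the scanner values of the same probes, and these rows were left out where the table was used.

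The files name 1984 kinds of probe. Of these, 597 name a mouse miRNA (589 name 1 and 8 name several), 1133 name miRNAs of other species alone, 216 have no name, and 19 capture other small RNAs. Most probes have 4 spots. The names are those of the array design and carry no genomic position. Probes were assigned to the gene Sfmbt2 by matching their names to miRNA genes of a mouse RefSeq table (GRCm38.p6), in which 575 of 595 tested probes found a gene.

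The mean spot signal was corrected for the median local background by the normexp method with an offset of 50, and each array was normalized by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots that the software marked as outliers were left out, and the spots of a probe were averaged on the log2 scale. Mouse probes well above background in the sample channel on at least 3 arrays entered the test. That flag was set for all of them, so the filter removed none; 2 probes, miR-675-5p and let-7e, were left out because outlier spots left too few values, which gave 595 tested probes. EAU was compared with naive by limma's lmFit and eBayes with group as the only term, two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The number of arrays limits the precision. Blank level means the median plus 3 median absolute deviations of the signal of blank and negative-control spots on each array, and a probe was above the blanks if at least 50% of its spots were; this measure was chosen after the flag was seen to separate nothing. A lower bound of a fold was taken where a probe was under the blanks on all arrays of a group, from the sample channel after loess and Aquantile: the mean of the brighter group against the mean of, per array, the higher of the lowest level above the blanks and the probe's own.

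The 18 lists of miRNAs were fixed before the data were examined: leukocyte, inflammation-inducible, the miR-183 cluster (miR-183, miR-96 and miR-182), neuronal, pigment epithelium, ocular surface and lens epithelium, erythroid, endothelial, smooth muscle and pericyte, striated muscle, the miR-17-92, miR-23/27/24, let-7, miR-15/16, miR-29, miR-30 and miR-181 groups, and the imprinted Dlk1-Dio3 cluster. MiR-155 stands in 2 lists. For each list the members past the threshold were counted over all probes and adjusted over the list alone. Lists with 3 or more tested probes that had a value on every array (14 of 18) were tested with camera at a preset correlation of 0.01 and with an estimated correlation, under which 0 lists passed, against 4 with the preset one. In the main fit the miR-183 cluster had no such test because miR-183 lacked a value on 1 array. It was tested in some alternatives, where it passed camera in 1 and did not pass without EAU replicate 1. Fry, which tests whether the members of a list move one way on balance, gave adjusted p-values of 0.00942 for let-7, 0.00942 for miR-181, 0.0196 for miR-30 and 0.0196 for the neuronal list. List means per array were compared by an exact permutation test.

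Named in the text are, in each direction, up to 15 probes past the threshold with no overlap between the groups, by size of the difference, and the up to 4 tested members of each list with the smallest p; let-7e, miR-30b, miR-124, miR-675-5p and the probes in the closing section outside this rule were chosen after their values were seen. The script was tested on simulated data of 592 probes with the observed spread, 60 of them changed, in 20 rounds: 76.2% of probes with a log2 change of 0.25 were called, 93% at 0.5 and 96.5% at 1, and 4.83% of calls fell on unchanged probes. The simulated noise was independent between probes and held no error shared by an array, a scan day or the normalization. These shares therefore test the script and do not carry over to the real arrays.

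The alternatives changed the background correction, the normalization within and between arrays, the use of the reference channel, the filter, the probe set, the averaging of spots, the outlier spots, the test, the source of the values and the replicates. A block for slide or scan day could not be fitted, because each slide holds 1 array and each scan day 1 group.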

Results

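Experimental autoimmune uveoretinitis (EAU) is an inflammatory disease of the retina, driven by T cells against retinal antigens, that is induced in susceptible mouse strains such as B10.RIII as a model of human uveitis. The series asked which microRNAs (miRNAs) differ between retinal cells of naive mice and of mice developing EAU on day 14. Retinal cells were harvested independently 3 times per condition from mice aged 8 weeks, and each RNA was labelled with the dye Hy3 and hybridised with one shared Hy5-labelled reference, a pool of the samples, to a locked nucleic acid capture array. The values are log2(Hy3/Hy5) per capture probe, so that a positive difference means more of a miRNA in EAU.

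The arrays were dim for most probes. The median spot brightness ranged from 54.8 to 93.1 in the sample channel, over a local background of 22 to 24, and from 33.7 to 38.2 in the reference channel, over a background of 29 to 30. The scanner software's flag for spots well above background was set for all 597 mouse miRNA probes on every array and so separated nothing. Measured against the blank and negative-control spots instead, 281 ± 15.9 mouse probes lay above the blanks in the naive samples and 299 ± 30.9 in the EAU samples (mean ± SD, n = 3 each), which is within the spread between arrays. Of the 597 probes, 208 were above the blanks on all 6 arrays and 213 on none. In the shared reference channel, 275 ± 42.9 mouse probes lay above the blanks on the naive arrays and 232 ± 66.0 on the EAU arrays. The 99th percentile of the reference signal was 778 ± 249 in naive and 471 ± 264 in EAU. EAU replicate 3 was lowest in both, with 162 probes and a 99th percentile of 195.

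The comparison of EAU with naive retinal cells gave higher miR-21 and miR-142-3p and lower miR-183, miR-204, miR-211 and members of the miR-30 family in EAU. MiR-21, an miRNA that inflammatory signalling raises in many cell types, rose 2.24-fold (log2 difference 1.16, SE 0.20), from a log2 ratio of -0.39 ± 0.11 in naive to 0.77 ± 0.39 in EAU (mean ± SD, n = 3 each; adjusted p = 0.0259). MiR-142-3p, which is made almost solely by cells of the blood lineage, rose 1.47-fold (log2 difference 0.56, SE 0.08; adjusted p = 0.0162). MiR-183, from a cluster that is abundant in photoreceptors, was lower by 2.59-fold (log2 difference -1.38, SE 0.28; adjusted p = 0.0496; 3 naive and 2 EAU arrays with a value). MiR-204 and miR-211, sister miRNAs of the retinal pigment epithelium, were lower by 1.65-fold and 1.41-fold (adjusted p = 0.0309 and 0.00644). The call of miR-21 was lost without naive replicate 1, 2 or 3 or EAU replicate 3 (adjusted p between 0.0595 and 0.0921), that of miR-142-3p without naive replicate 2 or EAU replicate 3 (0.0606 and 0.0666), that of miR-183 without naive replicate 1, 2 or 3 (0.111 to 0.156), and that of miR-204 without any one array except EAU replicate 1 (0.0551 to 0.111).

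Over all, 77 of 595 tested mouse probes passed an adjusted p of 0.05 in limma, 25 higher and 52 lower in EAU. In each of the 77 the naive and EAU arrays did not overlap, as was so for 274 of the 595 probes (46.1%, against 10% by chance for 3 against 3). Only 10 of the 77 differed by more than 1.5-fold, 3 higher and 7 lower. These folds are compressed: a simulated 4-fold rise of the sample signal of 60 probes, a log2 change of 2, came out at a median of 1.04. The background correction adds a constant to both channels. With the same constant but without loess, miR-21 differed by 2.72 (median centring) and 2.79 (no normalization), while let-7f differed by only -0.15 and -0.08. The parts of the constant and of loess in the compression were not separated. In the sample channel alone, miR-21 differed by 2.70 on the log2 scale (adjusted p = 0.00901) and miR-142-3p by 1.27, without passing there (adjusted p = 0.0521). Both were above the blanks on none of the 3 naive arrays and on all 3 EAU arrays, so that the rise in the sample channel was at least 3.69-fold for miR-21 and at least 1.85-fold for miR-142-3p, bounds that are open to a dye bias that differs between arrays, because no dyes were swapped.

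**Figure D1:**
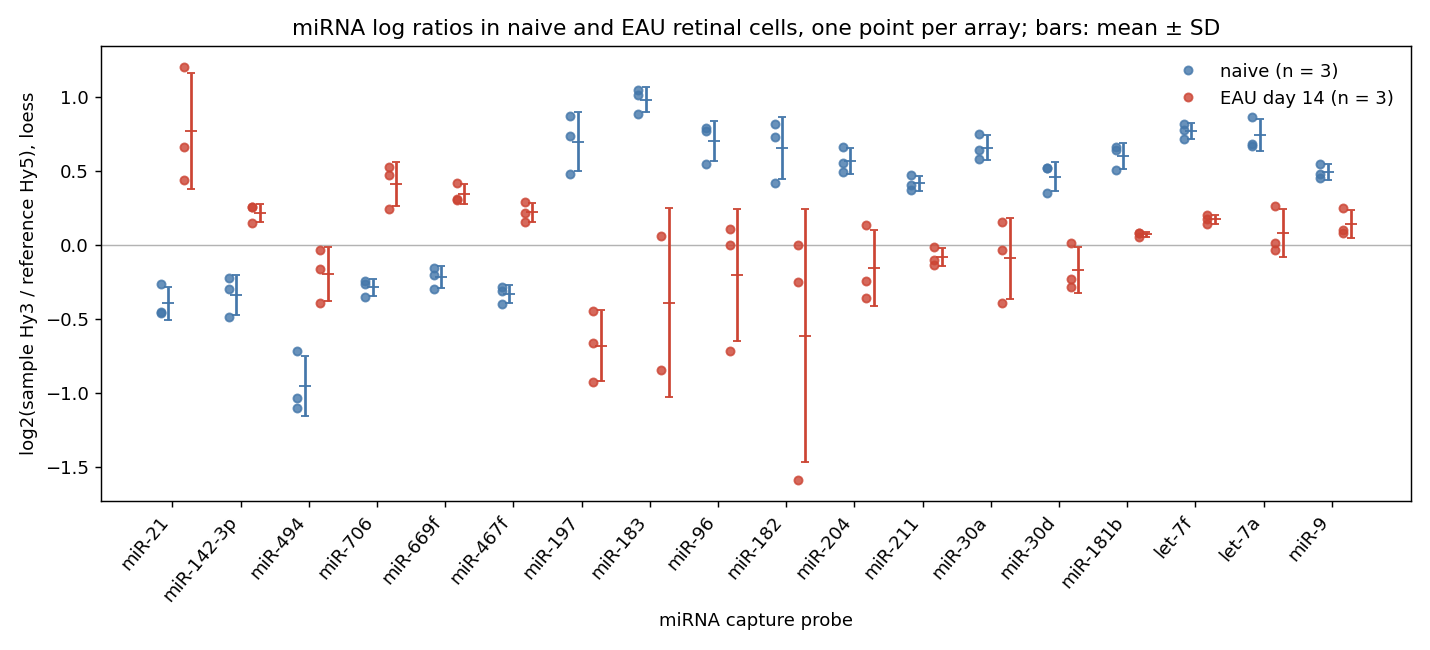
Log2 ratios of sample (Hy3) to pooled reference (Hy5) for 18 miRNA probes, with one point per array for naive (blue, n = 3) and EAU (red, n = 3, but 2 for miR-183) and bars for the mean ± SD. MiR-21 lies between a mean of -0.39 in naive and 0.77 in EAU, while miR-183, miR-96 and miR-182 lie lower in EAU with a wide spread between the EAU arrays; miR-96 and miR-182 did not pass the test.

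Among the other probes that rose, miR-494 (0.76, SE 0.14) and miR-706 (0.70, SE 0.08) had the largest differences after miR-21. They were followed by miR-669f (0.56), miR-467f (0.55), miR-466f-3p (0.54), miR-466i (0.49), miR-1192 (0.46), miR-503 (0.43) and miR-466d-5p (0.43). The probe shared by miR-297a*, miR-297b-3p and miR-297c* differed by 0.39, miR-881* by 0.38, miR-467g by 0.37 and miR-762 by 0.33. The adjusted p of these probes lay between 0.00644 for miR-669f and 0.0491 for miR-762. The rise of miR-494 was not seen in the sample channel alone, where the difference was 0.18 (adjusted p = 0.578).

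Among the probes that fell, miR-197 had the largest difference (-1.38, SE 0.16; adjusted p = 0.0132), and it passed the test without any single array. Besides miR-183, miR-204 and miR-211, given above, miR-30a (-0.75), let-7a (-0.66), miR-30d (-0.63), let-7f (-0.60), miR-30c (-0.57), miR-181b (-0.53) and miR-30e (-0.51) followed. MiR-145 (-0.45), miR-124* (-0.41), miR-129-3p (-0.38) and miR-9 (-0.35) completed the 15 probes with the largest decreases. The smallest adjusted p of all probes, 0.00301, was that of let-7f, which lay at 0.77 ± 0.05 in naive and 0.17 ± 0.03 in EAU (n = 3 each). Its difference was -0.15 with median centring (adjusted p = 0.757) and -0.08 with no normalization (adjusted p = 0.993), and that of let-7a -0.09 and -0.02. Of the 30 probes with the largest differences, 7 passed without any single array: miR-669f, miR-467f, miR-197, let-7f, miR-181b, miR-211 and miR-145. However, 0 of the 30 kept the call in all of the other processing settings, as each lost it in at least 1. Of these 7, miR-197 lost its call in 1 of 20 settings, miR-669f and miR-467f in 4, let-7f and miR-145 in 5, and miR-181b and miR-211 in 6.

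The number of calls depended on the normalization within each array: median centring in place of loess left 2 calls (1 higher and 1 lower), no normalization 25 (21 higher and 4 lower), and loess fitted on bright spots 24 (16 higher and 8 lower), while the deposited value table gave 82 with a different split (42 higher and 40 lower). The naive arrays were all scanned on one day and the EAU arrays on another, each array on its own slide, so scan day and group cannot be told apart, and leaving out naive replicate 1, 2 or 3 or EAU replicate 3 left 9, 15, 36 and 14 calls.

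Lists of miRNAs fixed before the data were examined were then compared. Besides the 30 probes with the largest differences, 10 list members passed (miR-128, miR-486, miR-143, miR-106b, miR-98, let-7g, miR-16, miR-181d, miR-329 and miR-541). Each lost its call on leaving out any of 2 to 6 of the 6 arrays in turn. Of the 3 members of the miR-183 cluster (miR-183, miR-96 and miR-182), miR-183 fell. MiR-96 (-0.91, adjusted p = 0.0605) and miR-182 (-1.27, adjusted p = 0.106) did not pass over all probes, and 3 of 3 passed adjusted over the list alone. Without EAU replicate 2 both passed at smaller differences, -0.65 (adjusted p = 0.0313) and -0.78 (adjusted p = 0.0485). In the sample channel alone the 3 members differed by -2.22, -1.79 and -2.11 for miR-183, miR-96 and miR-182, with adjusted p-values of 0.000886, 0.00881 and 0.0131. The mean of the cluster was 0.78 ± 0.03 in naive and -0.35 ± 0.61 in EAU (n = 3 each; exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows); on the EAU array without a value for miR-183 it was the mean of the other 2 members.

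Of the 14 tested miRNAs of the neuronal list, 3 fell, 11 did not pass and none rose; 4 passed adjusted over the list alone. The 3 were miR-9 (-0.35, adjusted p = 0.0199), miR-129-3p (-0.38, adjusted p = 0.0465) and miR-128 (-0.17, adjusted p = 0.03). MiR-129-3p lost its call in 11 of 20 settings and without any one of the 6 arrays. MiR-9 lost its call in 8 of 20 settings and on leaving out any of 4 of the 6 arrays in turn. MiR-128 was above the blanks on 1 of 3 naive and 1 of 3 EAU arrays, and its difference was -0.05 in the sample channel alone (adjusted p = 0.974), -0.08 with median centring (adjusted p = 0.709) and -0.01 with no normalization. The 13 members with a value on every array, which leave out miR-124, did not pass limma's camera test (adjusted p = 0.124, and 0.533 with an estimated correlation). The mean of all 14, miR-124 included, was -0.14 and their median -0.07. With the preset correlation the list passed in the sample channel alone (mean -0.31, adjusted p = 0.0285) and in the deposited value table (mean -0.30, adjusted p = 0.0255). The list mean was -0.06 without EAU replicate 3 and -0.22 without EAU replicate 1. The log2 ratio of miR-124 was 0.16 on EAU replicate 1 and -2.03 on EAU replicate 3. MiR-129-5p differed by -0.11 (adjusted p = 0.0728). MiR-124, the most abundant miRNA of neurons, had a log2 difference of -0.67 with an SE of 0.69 (adjusted p = 0.541; 3 naive and 2 EAU arrays with a value). Its raw sample signal was 47407 ± 3200 in naive and 13222 ± 6385 in EAU, and its raw reference signal 4788 ± 1631 and 1860 ± 1556 (mean ± SD, n = 3 each), so both channels were dimmer in EAU at this probe. In the sample channel alone miR-124 differed by -2.09 (adjusted p = 0.00881). Outlier spots at this probe numbered 0, 3 and 3 on naive replicates 1 to 3 and 3, 4 and 3 on EAU replicates 1 to 3. The raw signals include these spots. The log2 ratio and the value in the sample channel alone leave them out, and so rest on few spots on most arrays.

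Both tested miRNAs of the pigment epithelium list, miR-204 and miR-211, fell, also adjusted over the list alone. Both members of the smooth muscle and pericyte list fell too, miR-145 (adjusted p = 0.00644) and miR-143 (-0.27, adjusted p = 0.03), and both passed adjusted over the list alone. MiR-143 lost its call in 9 of 20 settings and without any one array except EAU replicate 1. It was at -0.11 with median centring and -0.05 with no normalization. None of the 2 endothelial miRNAs passed (miR-126-3p -0.06, miR-126-5p -0.01), nor did any of the 4 of striated muscle, among them miR-133b (-0.15), miR-206 (-0.14), miR-133a (-0.28) and miR-1 (-0.25), or of the 8 of ocular surface and lens epithelium, for which miR-203 (-0.07), miR-205 (-0.19), miR-200a (-0.08) and miR-141 (0.02) had the smallest p-values. None of these 3 lists had a member that passed adjusted over the list alone. In camera, striated muscle had an adjusted p of 0.158 and epithelium of 0.76. In the deposited value table striated muscle passed (adjusted p = 0.0255), with miR-133a at -0.84 (adjusted p = 0.0067). The means of the endothelial and epithelial lists change sign with median centring and with loess on bright spots.

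Of the 7 leukocyte miRNAs, 1 rose (miR-142-3p) and 6 did not pass; 2 passed adjusted over the list alone. MiR-142-5p, the other arm of the same hairpin, differed by 0.47 (adjusted p = 0.0581), was above the blanks on none of the 3 naive and all 3 EAU arrays, and differed by 1.05 in the sample channel alone (adjusted p = 0.00881). With the naive arrays under the blanks, its rise in the sample channel holds as a lower bound only, at least 1.40-fold. MiR-155 (0.09, adjusted p = 0.141) and miR-342-5p (0.13, adjusted p = 0.153) did not pass, and miR-155 was above the blanks on none of the 6 arrays. The list had a camera adjusted p of 0.0568, and of 0.533 with an estimated correlation. With the preset correlation it passed the threshold in 8 of 14 alternatives, among them the sample channel alone (adjusted p = 0.00485).

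Of the 6 inflammation-inducible miRNAs, 1 rose (miR-21) and 5 did not pass; 2 passed adjusted over the list alone. MiR-146b, which Toll-like receptor signalling induces in myeloid cells, had a difference of 0.18 (adjusted p = 0.0777), and miR-147 of 0.05 (adjusted p = 0.388). Of the 6, only miR-21 was above the blanks on at least 3 arrays, so the list had too few members for camera under that filter. The list, whose mean was 0.25 and median 0.07, was higher in camera (adjusted p = 0.0467; adjusted p = 0.533 with an estimated correlation), and lost this call without naive replicate 1, naive replicate 3 or EAU replicate 1 (adjusted p between 0.0546 and 0.074). Of the 3 erythroid miRNAs, 1 passed, also adjusted over the list alone: miR-486 was lower (-0.23, adjusted p = 0.0465), a sign that turned with median centring (0.10), with no normalization (0.17) and in the sample channel alone (0.13). MiR-451 differed by 0.14 (adjusted p = 0.244) and miR-144 by 0.01. The erythroid list had a camera adjusted p of 0.976; its mean was -0.03 and its median 0.01, and camera, which compares the t statistics of the list with those of the other probes, gave the direction up. Its mean turned positive with median centring, with loess on bright spots, in the sample channel alone and in the deposited value table.

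**Figure D2:**
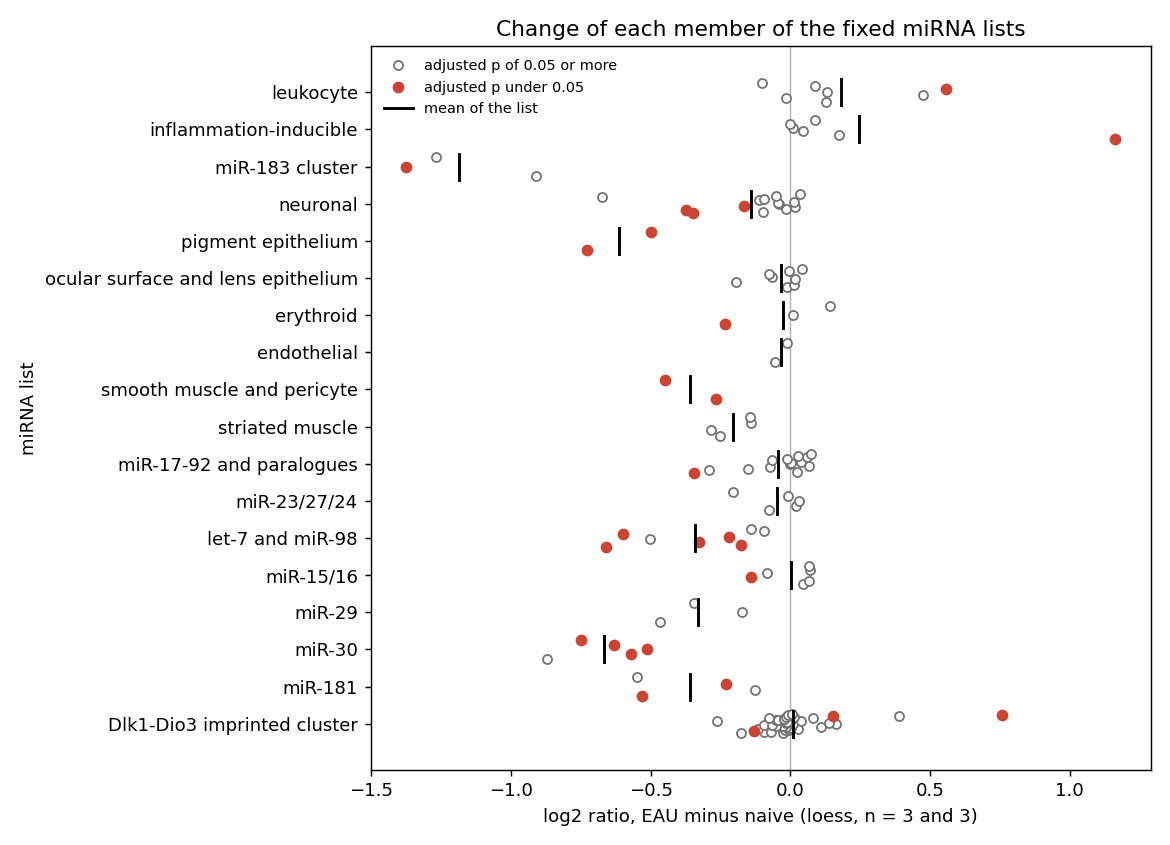
Log2 difference, EAU minus naive, of each tested member of the 18 fixed lists, with filled points for members with an adjusted p under 0.05, open points for the rest and a black line for the mean of the list. The means of the miR-183 cluster (-1.18), the miR-30 family (-0.67) and the pigment epithelium list (-0.61) lie farthest below 0, and that of the inflammation-inducible list (0.25) farthest above.

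Families of broadly expressed miRNAs were compared in the same way. Of the 5 members of the miR-30 family, 4 fell and miR-30b did not pass (-0.87, adjusted p = 0.0789), while 5 passed adjusted over the list alone. The family was lower in camera (adjusted p = 0.00695; adjusted p = 0.533 with an estimated correlation). Of 8 tested members of the let-7 family and miR-98, 5 fell, 3 did not pass and 7 passed adjusted over the list alone, with let-7g (-0.33) and miR-98 (-0.22) beside let-7a and let-7f. The family was lower in camera (adjusted p = 0.00147; adjusted p = 0.533 with an estimated correlation), but not with median centring (mean -0.01, adjusted p = 0.599). In the sample channel alone the family was lower too (mean -0.26, adjusted p = 0.0298), with let-7g at -0.54 (adjusted p = 0.00901), while let-7f (-0.34, adjusted p = 0.453) and let-7a (-0.24, adjusted p = 0.288) did not pass. Let-7e had too many outlier spots to be tested.

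Of the 4 members of the miR-181 family, 2 fell, miR-181b and miR-181d (-0.23, adjusted p = 0.0453), and miR-181a (-0.55, adjusted p = 0.104) and miR-181c (-0.13, adjusted p = 0.105) did not pass; 4 passed adjusted over the list alone. The family was lower in camera (adjusted p = 0.0345; adjusted p = 0.533 with an estimated correlation), and lost the call without naive replicate 3 (adjusted p = 0.0648) or EAU replicate 1 (adjusted p = 0.0740) and with the filter above the blanks on at least 3 arrays (adjusted p = 0.0575). MiR-181d was at 0.017 in the deposited value table. None of the 3 miR-29 members passed (miR-29c -0.47, miR-29b -0.17, miR-29a -0.35), with 1 passing adjusted over the list alone. The camera adjusted p was 0.199, and 0.598 with an estimated correlation. In the sample channel alone all 3 passed (-0.98, -0.65 and -0.62 for miR-29c, miR-29b and miR-29a, with adjusted p-values of 0.00938, 0.00881 and 0.0325), and the list passed camera there (mean -0.75, adjusted p = 0.000882) and with loess on bright spots (mean -0.24, adjusted p = 0.0438).

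Of 14 miRNAs of the miR-17-92 cluster and its paralogues, 1 fell, miR-106b (-0.34, adjusted p = 0.0384), also adjusted over the list alone. It lost its call in 10 of 20 settings and without any one array except EAU replicate 2. MiR-17* (-0.15), miR-20a (0.07) and miR-92a (-0.29) did not pass. The list mean was -0.05 and its median 0.00052, with a camera adjusted p of 0.602 in the direction of the median, and the mean turned positive with loess on bright spots and in the deposited value table. Of 6 members of the miR-15/16 family, 1 fell, miR-16 (-0.14, adjusted p = 0.0215), also adjusted over the list alone, with a sign that turned under median centring (0.0038) and with no normalization (0.072). MiR-322 (0.07), miR-497 (0.04) and miR-195 (-0.09) did not pass, and the camera adjusted p of the family was 0.602. None of 5 members of the miR-23/27/24 clusters passed, also adjusted over the list alone (miR-23b -0.08, miR-24 -0.21, miR-27a 0.02, miR-23a 0.03; camera adjusted p = 0.976), and their mean (-0.05) turned positive with median centring and with loess on bright spots.

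Of 39 miRNAs of the imprinted Dlk1-Dio3 cluster, 2 rose, miR-494 and miR-329 (0.15, adjusted p = 0.0323), and 1 fell, miR-541 (-0.13, adjusted p = 0.0487); 2 passed adjusted over the list alone. MiR-541 was above the blanks on 1 of 3 naive and 0 of 3 EAU arrays, and lost its call in 12 of 19 settings and without any one of the 6 arrays. MiR-329 lost its call in 10 of 20 settings and without any one of the 6 as well. MiR-299 (-0.09) did not pass, and the cluster as a whole had a camera adjusted p of 0.976, in the direction of its mean (0.0088) against that of its median (-0.02); the mean turned negative in the sample channel alone, with no background correction and without EAU replicate 3. In per-array means, 12 of the 18 lists had naive and EAU arrays that did not overlap. Chance gives 10%, but 46.1% of the single tested probes did not overlap either, and no share for random lists was computed. The smallest p that an exact permutation test of 3 against 3 allows is 0.1.

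The array also held 19 probes for small RNAs other than miRNAs, of which 12 were above the blanks on all 6 arrays and 6 on none. Their median difference was 0.0098, with 11 higher and 8 lower in EAU, but dim probes stay near 0 and the rest went both ways, so the median does not check the scaling. SNORD14B stood at 0.23 ± 0.24 in naive and -1.08 ± 0.14 in EAU, SNORD13 at 0.54 ± 0.10 and -0.03 ± 0.24, and SNORD3@ at -0.04 ± 0.13 and 0.39 ± 0.04 (mean ± SD, n = 3 each; not tested). The 2 U6 snRNA probes differed by 0.26 and 0.24, and 5S rRNA by 0.27 with an SD of 0.83 in EAU. The median difference rose to 0.14 with median centring and 0.21 with no normalization.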

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

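Of the tests below, only the count of other splits was chosen before its result was seen; the others were chosen after.

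Signals outside the comparison came from 3 sources. Of 1345 probes that name no mouse miRNA, 72 passed an adjusted p of 0.05 in one limma fit over all non-control probes, 18 higher and 54 lower in EAU; the smallest adjusted p was that of the human miR-320d probe (0.48, SE 0.03, adjusted p = 0.00692), and the human miR-220b probe fell by 1.64 on the log2 scale. Of 119 probes for viral miRNAs, 30 were above the blanks on all 6 arrays, the brightest being that for ebv-miR-BART2-3p at 2964 ± 492 in naive and 2710 ± 1128 in EAU (raw sample signal, mean ± SD, n = 3 each), and 4 of the 119 passed the test. In the deposited value table, 36 rows, 9 of them for mouse miRNAs such as miR-342-5p, held ratios above 32 on every array, although 21 of the 36 probes were above the blanks on fewer than 3 arrays.

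The first pattern weighed is the set of 77 called probes: the real split of the 6 arrays gave 77 calls and the highest of the other 9 splits 0, so 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. A shift of the reference channel that differs between probes is argued against only as the main source of the ratio changes, on average over the 77. Over the 77 probes, the change in Hy5 alone had a slope of -0.0253 on the ratio change (95% bootstrap interval -0.145 to 0.0616). The slope of Hy3 alone was 1.56. As an average, the Hy5 slope cannot decide about single probes. MiR-494 differed by 0.76 in the ratio and 0.18 in Hy3 alone, and miR-486 by -0.23 and 0.13. Hy5 was quantile-normalized across the arrays beforehand, which removes a shift of the whole channel, so the slope cannot decide about such a shift. An offset of dim spots was first tested by calls among dim viral and dim mouse probes in the fit over all non-control probes (1 of 74 and 8 of 299, Fisher's exact test, p = 1). It was then tested by calls among bright and dim mouse probes in the fit over mouse probes (63 of 296 and 14 of 299). Both decide nothing, since dim probes are compressed toward 0. A further test, chosen after these, argues against an offset as the cause of all calls: 29 of the 77 probes would need, at the 95% limit of their change nearest 0, in Hy3 as well as in Hy5, a larger offset than the largest difference in blank level between a naive and an EAU array (36.6 in Hy3 and 4.78 in Hy5), while the other 48 stay open. MiR-142-3p is among these 48, with an offset of 28.4 needed in Hy3 and 15.1 in Hy5. So are miR-881*, miR-762, miR-124* and miR-129-3p of the 30 probes with the largest differences. Of the other named probes, miR-128, miR-143, let-7g, miR-98, miR-181d, miR-106b, miR-486, miR-16, miR-329 and miR-541 are among them. The same holds for miR-466c-5p, miR-31 and miR-741, named below. Scan day and disease cannot be told apart, because 0 scan days hold arrays of both groups.

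The second pattern is the lower level of miRNAs enriched in the retina. RNA of infiltrating cells may dilute retinal RNA, which would lower these miRNAs by similar factors in the sample channel. Over members above the blanks on all arrays, the miR-183 cluster differed by -2.04 ± 0.22 (3 probes) and the neuronal list by -0.54 ± 0.72 (7 probes; exact permutation test, p = 0.0167), which alone would argue against dilution, but 5 of the 7 neuronal probes were too dim to show a fall of that size. The test was limited to the brighter probes after that p was seen: of the other 2, miR-124 differed by -2.09 and miR-9 by -0.66, and the exact permutation test over 5 probes gave p = 0.2, where the smallest possible is 0.1. The value of miR-124 also rests on the few spots left without outliers, with none left on EAU replicate 2. Dilution, loss of photoreceptors and lower expression therefore stay open.

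The third pattern is the rise of miR-142-3p and miR-21. Blood left in the tissue may bring miRNAs of blood cells, and would then raise those of red cells as well. In the sample channel alone miR-451 differed by 0.35 (95% interval 0.06 to 0.65) and miR-486 by 0.13 (-0.24 to 0.49), against 1.27 for miR-142-3p, but miR-142-3p was above the blanks on no naive array and its own interval runs from 0.554 to 1.98, which overlaps the highest upper limit of the red-cell miRNAs, 0.647, so blood cannot be told apart from infiltrating leukocytes for it. The change of miR-21, 2.70 (1.9 to 3.5), lies above the limits of both red-cell miRNAs. As miR-21 was above the blanks on no naive array, its rise holds as a lower bound only, at least 3.69-fold. This goes against blood as its source. However, the red-cell miRNAs lie near the blanks and their levels in blood relative to miR-21 were not measured, so blood is not excluded. Infiltrating leukocytes, part of the disease that the design compares, stay open too, and in the sample channel alone miR-223 of myeloid cells differed by 0.62 (adjusted p = 0.206) and miR-150 of lymphocytes by 0.19 (adjusted p = 0.389), against 0.13 and -0.10 in the ratio (adjusted p = 0.75 and 0.289).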

How the results depend on the processing

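The filter above the blanks, the median-centred sample channel and the reference channel alone were added after the data were seen. A block for slide or scan day, and a replicate block for list means, were not run. Dropping the filter, or asking for the flag on all 6 arrays, removed no tested probe and moved nothing. Of the 77 called probes, 77 kept their sign without any one array, 71 with median centring, 70 in the sample channel alone and 65 with no normalization. The count of calls (25 higher and 52 lower) came to 22 with the scanner software's processed signals (8 and 14), 2 with median centring (1 and 1), 25 with no normalization within array (4 lower), 24 with loess on bright spots (16 and 8), 123 with all non-control probes (39 and 84 of 1940 tested, of which 51 mouse probes, 21 and 30), 48 with spot medians (27 lower), 7 in the sample channel alone with median centring (1 and 6) and 0 in the reference channel alone (0 and 0; 33 at an unadjusted p under 0.05 in limma), while the deposited value table gave 42 higher. The sample channel alone with quantile normalization called 56, of which 28 were among the 77. Leaving out one array gave 9 to 79 calls, 4 to 25 higher and 5 to 56 lower. With the replicate number as a block, 2 probes passed (0 higher and 2 lower; 174 at an unadjusted p under 0.05). The deviations of same-numbered samples correlated over probes at 0.21, -0.16 and 0.29, and those of differently numbered samples at -0.45 to 0.29. These few values do not show a pairing by number and cannot exclude one. The lists past the threshold in camera numbered 7 in the sample channel alone, 8 in the deposited value table, 2 with the filter above the blanks and 2 to 5 without one array, against 4. The lists that could be tested differed between these settings, so the counts are not over one set of lists. Lists with non-overlapping arrays numbered 7 with median centring and 12 to 15 without one array, against 12. Detected mouse probes numbered 290.2 per array above the blanks against 597, and 1946 over all non-control probes. The median of the small RNA probes was 0.14 with median centring and 0.21 with no normalization. Among named probes that passed, signs turned for miR-486 with median centring (0.10), no normalization (0.17), the sample channel alone (0.13) and the same median-centred (0.19), for miR-16 with median centring (0.0038) and no normalization (0.072), and for miR-181d in the deposited value table (0.017). Named probes that did not pass turned as well, such as miR-206 (0.25) and miR-24 (0.19) with no normalization. The cause was not tested. Of the 15 higher and 15 lower named probes, miR-197 lost its call in 1 of 20 settings (the replicate block) and in 0 of 6 left-out arrays, miR-21 in 3 and 4, miR-142-3p in 2 and 2, and miR-183 in 7 and 3. Differences of probes near the blanks, 299 of 595, are limited by the signal over background.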

Other observations

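Probes for miRNAs encoded inside the gene Sfmbt2, a cluster that holds much of the miR-297, miR-466, miR-467 and miR-669 families of rodents, were seen among the miRNAs that rose; this grouping was chosen after the data were seen, so no test of it is given. Of 37 tested probes of the cluster, 8 rose (21.6%) and 0 fell, against 17 of 558 other mouse probes that rose (3.05%). The 8 include miR-669f (0.56), miR-466f-3p (0.54), miR-466d-5p (0.43), miR-466c-5p (0.33) and miR-669e (0.33), and 31 of the 37 lay above 0, with a median of 0.12. Among probes above the blanks on all 6 arrays the shares were 6 of 18 and 13 of 188. Of 7 family probes that were not matched to a gene inside Sfmbt2, 4 rose, among them miR-467f (0.55), miR-466i (0.49) and miR-466a-5p (0.33). The matching was by name, and a shared probe that names miR-466a-3p was counted inside, so some of the 7 may belong inside as well. The median of the cluster was positive in all settings run, from 0.07 without EAU replicate 2 to 0.57 with no normalization, but the number of its probes that passed was 0 with median centring, with the replicate block and in the median-centred sample channel, 1 with the scanner software's processed signals and without naive replicate 1 or naive replicate 2, and 2 without EAU replicate 3. A probe of the cluster was called lower with no background correction, without naive replicate 3 and without EAU replicate 1. Members of these families resemble each other in sequence, so their probes are not independent measurements.

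Some other called probes outside the fixed lists were under the blanks on all EAU arrays. MiR-741 was above the blanks on 3 of 3 naive arrays and 0 of 3 EAU arrays (-0.17, adjusted p = 0.0465), at least 1.24-fold higher in naive in the sample channel, and miR-31 on 2 and 0 arrays (-0.17, adjusted p = 0.0199).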
